A study of Mus musculus with 17 samples.

How the data were processed

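Polyadenylated RNA from 17 mouse livers was sequenced. The labels name 3 groups: wild-type B6 mice aged 2 months (6 libraries), wild-type B6 mice aged 2 years (5 libraries) and miR-29 transgenic mice aged 2 months (6 libraries). Per the labels' protocols, RNA was purified with a Norgen column kit, and the libraries came from 2 batches. Batch A (10 libraries) was made with the Illumina TruSeq polyA kit at the University of North Carolina. Batch B (7 libraries) was made with the NEBNext Ultra II Directional kit at Cornell University. All 7 batch B libraries came from males. The whole set held 12 males and 5 females, and 1 of the transgenic animals was female. The labels call each library a separate sample and do not state that each came from a separate animal. P-values therefore measure the spread between these libraries.

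Per the submitters' processing notes, STAR 2.5.3a, Salmon 0.6.0 and DESeq2 were used with the mm10 build. The role of each tool, the annotation release and the strand setting were not given in the sources used here. The authors deposited 1 table of normalized signal per gene and library, named as DESeq2 normalized counts, for 48440 Ensembl genes. Between 8.0% and 56.2% of the low values of a library lay within 0.1 of a whole step of 1 read, so whole reads could not be recovered, and sequencing depth is unknown. The normalized values of a library summed to 28077001 to 38594453 in batch A and to 29552390 to 44543936 in batch B. These totals are not read depths, so counting intervals and detection floors were not computed. The 10 highest genes took 17.8% to 27.5% of a library's total.

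The authors also deposited 2 tables of comparisons. One held 15814 genes for 2-year-old against 2-month-old wild type, the other 15714 genes for transgenic against wild type. Per the file headers, each gives the authors' log2 fold change with its standard error, a test score and a p-value with its adjusted value. The tables' names state that the authors corrected for batch and sex. The test score equalled the log2 fold change divided by its standard error in every row. Genes in these deposited tables had a mean normalized signal above 5. These tables served only as an alternative to the fit described next.

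Identifiers were matched to a reference table of mouse gene names, and 48058 of 48440 were found. Symbols came from the deposited table except for 27 that had been turned into dates, for which the reference table's symbols were used where it had one. Coordinates and 3′ UTRs are those of the GENCODE M21 annotation of GRCm38, the assembly that mm10 names, counted from 1. The sum over all gene rows and each library's share of its 10 highest genes were computed before any filter.

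Each comparison was tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a mean-variance trend) on log2(normalized value + 1). The 14588 genes with a mean value of at least 10 over the 17 libraries entered the fit. Group, batch and sex were the terms, and all 17 libraries shared one estimate of the spread. A gene was called at a two-sided Benjamini-Hochberg adjusted p under 0.05, and "rose", "fell" and "changed" are used for called genes. Fold changes are adjusted for batch and sex and lie on the log2(value + 1) scale, which understates changes of low genes. Means ± SD are of unadjusted normalized values. Because the groups differ in their share of males and in batch, an adjusted fold change can differ from the ratio of the group means. Within-batch values came from fits of batch A or batch B alone. Differences of an effect between sexes or batches were tested with an interaction term.

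A total of 43 gene lists covering pathways and cell types were fixed before the data were examined, together with 5 sex-linked genes that check the labels. Of these lists, 42 had at least 3 measured members and were tested with camera at a preset inter-gene correlation of 0.01. Camera with an estimated correlation and fry were alternatives. Counts of called members are given over all genes tested and adjusted over the list alone. The comparison of the 2 fold changes used correlation, covariance and the count of genes called in both. It was set beside 100 simulated draws of unchanged groups that share the controls, beside the overlap of independent lists, and beside 8 fits with the 6 controls split into balanced sets of 3.

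The miR-29 seed match TGGTGCT was searched in the longest annotated 3′ UTR of at least 30 nucleotides, which 20662 genes had. The mean expression difference of genes with a site against genes without, adjusted for UTR length and GC content by regression across genes, was computed per library. The group difference of this score was tested by an exact two-sided permutation of labels within batch and sex. A site of 7 bases can be shared with any factor of the same seed.

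Named genes followed a rule fixed in the same way. For the age and the transgene comparisons it took the 10 largest rises and the 10 largest falls among called genes with a mean of at least 50 in the compared libraries and one direction in both batches. It left out predicted genes, immunoglobulin and T cell receptor segments and pseudogenes. It added up to 2 rises and 2 falls per called list and for 6 lists of prior interest, or the member with the smallest p of a called list with no called member. It always included 11 matrix, methylation, senescence and growth genes, the miR-29 host rows and the sex-linked genes. Of the genes called in both comparisons it took up to 10 with one direction and up to 5 with opposite directions. Some results that the rule covers are not reported here. Genes named outside this rule are said to be chosen after their values were seen; members of a list given only as examples beside its count were likewise chosen after that.

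The limma and camera steps were tested on simulated data with the real genes, spreads and design. Noise was drawn for each gene on its own, also for the seed-site score, so the simulated genes lack the correlation of real ones. The draws were not repeated, so the rates below hold only for genes that vary apart. They do not test camera's preset correlation. In the age comparison, over 14588 genes, 26.1% of genes changed 2-fold, 83.6% of those changed 4-fold and 88.6% of those changed 8-fold were recovered, and 3.0% of calls were false. In the transgene comparison, over 14588 genes, the shares were 30.8%, 82.0% and 93.4%, and 5.8% of calls were false. The seed-site score returned -0.195 for a simulated shift of -0.2 over 12927 genes. Both 2-fold rates mean that small changes were mostly missed at this number of libraries.

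Alternatives fixed at the same time covered the pseudocount, the filter on low values, quantile and upper-quartile scaling, the batch and sex terms, each batch alone, males alone, quality weights, the replicate number as a block, only the compared groups, the authors' tables, and leaving out each library in turn. Alternatives added after the data were seen were removal of the transcript length and GC trend, 1 residual component as a covariate, leaving out the 2 batch B libraries nearest batch A, leaving out the only transgenic female, and further settings of the interaction tests. Regroupings within batch and sex, counts of sex-biased list members by sex and medians of the sex-biased lists without each old library were also added then. Scaling moved the median fold change of all genes by less than 0.1 on the log2 scale. No library columns were identical, and rank correlations between libraries of one group ranged from 0.818 to 0.991 with a median of 0.917. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with pandas 2.3.3 and numpy 2.4.6.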

Results

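The series measured polyadenylated RNA in the livers of wild-type B6 mice at 2 months (6 libraries) and at 2 years (5 libraries), and of 2-month-old mice that carry a miR-29 transgene (6 libraries). B6 is the common inbred black laboratory strain. The microRNA miR-29 lowers messages that carry its seed match, among them collagens and DNA methyltransferases. The series title presents miR-29 as a driver of ageing phenotypes, so the design asks which liver genes differ with age, which differ with the transgene, and whether the 2 sets of changes resemble each other. Values are the authors' normalized counts, whose totals ran from 28077001 to 44543936 per library, and depth is unknown. Libraries came from 2 batches that differ in kit and sequencing site, and all 7 batch B libraries were male.

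The labels' sexes matched the sex-linked genes in every library. Xist, the RNA of the inactive X chromosome, lay between 13062.5 and 23136.9 normalized counts in the 5 females and at or below 66.5 in the 12 males. The Y-linked Ddx3y lay at 839.4 or above in males and at or below 42.2 in females. Kdm5d, Uty and Eif2s3y, also on the Y chromosome, were at or below 21.6, 19.1 and 44.6 in females and at or above 72.9, 191.4 and 817.9 in males. The miR-29 precursor genes (Mir29a, Mir29b-1, Mir29b-2 and Mir29c) are listed at 0 in all libraries, so the transgene's product was not measured here.

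Age was examined first, as 2-year-old against 2-month-old wild-type liver. Old livers had more message of the cell cycle inhibitor Cdkn2a, of immunoglobulin heavy chains and of the fatty acid transporter Cd36, and less of the male-biased transporter Slco1a1 and the glucuronosyltransferase Ugt2b38. In total 21 of 14588 genes passed the test, 14 higher and 7 lower, while 1274 had an unadjusted p under 0.05 where 729 would be expected by chance. Cdkn2a (chr4:89274471-89294653), which encodes p16 and p19, rose from 1.77 ± 2.13 (SD, n = 6) to 31.7 ± 15.8 normalized counts (SD, n = 5), a log2 fold change of 3.85 ± 0.60 (SE, limma adjusted p = 0.0139). Cd36 (chr5:17781690-17888801) rose from 1347 ± 1305 to 3799 ± 2230 (log2 fold change 1.87 ± 0.29, adjusted p = 0.0139). Slco1a1 (chr6:141907282-141946962) fell from 11130 ± 8687 to 1270 ± 2596 (log2 fold change -5.50 ± 0.90, adjusted p = 0.0161). Ugt2b38 (chr5:87409942-87424203) fell from 980.2 ± 801.8 to 29.7 ± 38.9 (log2 fold change -4.81 ± 0.84, adjusted p = 0.0307).

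Among the other rises with age were the cadherin Cdh19 (chr1:110888326-110977584, log2 fold change 5.79 ± 0.77), the transcription factor gene Dmrta1 (5.10 ± 0.72), the cytochrome P450 Cyp2c38 (2.74 ± 0.44), the NKG2D ligand Raet1e (2.46 ± 0.35), the efflux pump Abcc4 (1.75 ± 0.33) and the Rac exchange factor Tiam2 (1.28 ± 0.24). Among the other falls were E-cadherin, Cdh1 (chr8:106603351-106670246), at -2.70 ± 0.38, the sorting receptor Sort1 at -1.76 ± 0.27, Casc4 at -1.55 ± 0.29 and the complement component C8b at -1.47 ± 0.26. Their limma adjusted p ranged from 0.0066 to 0.0427. Cyp2c38, Ugt2b38 and Slco1a1 belong to families of near-identical copies, so the value of a single member is uncertain. Batch A alone called 1 gene and batch B alone, with 2 libraries on each side, called 0, with 3764 genes at an unadjusted p under 0.05.

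Several lists were called with age at a preset correlation, and none with an estimated one. Other groupings of the same libraries called a median of 11 lists at the preset correlation, against 17 here. Camera p-values at that setting therefore overstate the evidence. Of 17 male-biased liver genes, 2 fell (11 adjusted over the list alone), and all 17 fitted values were below 0, with a median log2 fold change of -3.11 (-2.36 in batch A, -2.93 in batch B; camera adjusted p = 1.2e-16, adjusted p = 0.164 with an estimated correlation). The batch B value comes from 2 old males that differed, with Cyp4a12a, chosen after its values were seen, at 45.5 in library 4 and 2469 in library 5 against 2371.2 and 2661.2 in the young males of that batch. Without library 4 the list's median over both batches was -2.28. None of 22 female-biased genes passed limma's test (1 adjusted over the list alone, 7 at an unadjusted p under 0.05), while their median was 2.00 (adjusted p = 5.57e-09 and, with an estimated correlation, adjusted p = 0.391). The growth-hormone-dependent repressor Cux2 had the smallest p among them, with a log2 fold change of 3.90 ± 0.91 and adjusted p = 0.125. Of 17 B and plasma cell markers, 2 rose (7 adjusted over the list alone), with a median of 1.26 and adjusted p = 0.112 with an estimated correlation. These were the heavy-chain genes Ighm, from 175.6 ± 92.5 to 1886 ± 1100 (log2 fold change 3.27 ± 0.42, adjusted p = 0.0066), and Ighg2c (3.57 ± 0.66, adjusted p = 0.0427).

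None of 15 neutrophil markers passed (0 adjusted over the list alone, 7 higher at an unadjusted p under 0.05). Their median was 1.77 (adjusted p = 0.311 with an estimated correlation), and Retnlg had 3.15 ± 0.97 with adjusted p = 0.346. Of 28 acute-phase genes none passed limma's test (1 adjusted over the list alone, 6 at an unadjusted p under 0.05). The median was 0.87 (adjusted p = 0.504 with an estimated correlation), and Serpina3m had 1.32 ± 0.31 with adjusted p = 0.125. Of 20 sinusoidal endothelial markers, Cd36 rose (3 adjusted over the list alone; median 0.54, adjusted p = 0.371 with an estimated correlation). Cd36 is also the 1 called member of 29 fatty acid oxidation genes (5 adjusted over the list alone; median 0.30, estimated-correlation adjusted p = 0.523). Abcc4 is the 1 called member of 26 NRF2 and glutathione genes (2 rises and 1 fall adjusted over the list alone; median 0.17, estimated-correlation adjusted p = 0.642). Of 22 senescence and secretory genes, Cdkn2a rose (1 adjusted over the list alone; median 0.78, adjusted p = 0.219 with an estimated correlation). For the other members of prior interest, Cdkn1a had 0.31 ± 0.71 (adjusted p = 0.895) and Lmnb1 0.47 ± 0.40 (adjusted p = 0.706).

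Other lists were called by camera with the preset correlation, not with an estimated one, and had no member past limma's test over all genes. Of these, fry called the lysosome genes (adjusted p = 0.0303). Among the lists described before, fry called the male-biased genes (adjusted p = 0.0303) and the B and plasma cell markers (adjusted p = 0.0152). For 43 nuclear OXPHOS genes the median was -0.46 (0.03 in batch A, -1.23 in batch B; adjusted p = 0.523 with an estimated correlation), with 5 members lower at an unadjusted p under 0.05. Its member with the smallest p was Ndufb3, at -0.75 ± 0.29 and adjusted p = 0.503. For 44 ribosomal proteins it was -0.32 (0.13 and -1.15; estimated-correlation adjusted p = 0.694), with 0 members at an unadjusted p under 0.05, and Rpl38 had -0.55 ± 0.32. For 21 collagens it was -0.31 (-0.54 and 0.22; estimated-correlation adjusted p = 0.588; 2 lower adjusted over the list alone and 5 unadjusted). Col1a2 had -1.12 ± 0.28 with adjusted p = 0.156, Col1a1 -1.32 ± 0.48 and Col3a1 -1.40 ± 0.58. Medians of the remaining lists of this kind were 0.28 for 25 lysosome genes (Grn 0.71 ± 0.21), 0.68 for 19 monocyte and recruited macrophage markers (Trem2 1.83 ± 0.43), -0.30 for 25 unfolded protein response genes (Sdf2l1 -1.28 ± 0.36), 0.34 for 20 circadian genes (Noct 1.99 ± 0.46) and -0.18 for 36 other matrix genes (Mfap4 -1.61 ± 0.52). Their adjusted p with an estimated correlation was 0.17, 0.504, 0.391, 0.391 and 0.608. Members past the test adjusted over the list alone were 0, 1, 0, 1 and 0, and 3, 3, 4, 3 and 10 had an unadjusted p under 0.05. The matrix genes Eln and Sparc had -1.11 ± 0.38 and -0.70 ± 0.28, Col4a1 0.09 ± 0.26, the methyltransferases Dnmt3a and Dnmt3b 0.14 ± 0.33 and -0.20 ± 0.38, and Igf1 0.16 ± 0.22. None of these passed.

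**Figure D1:**
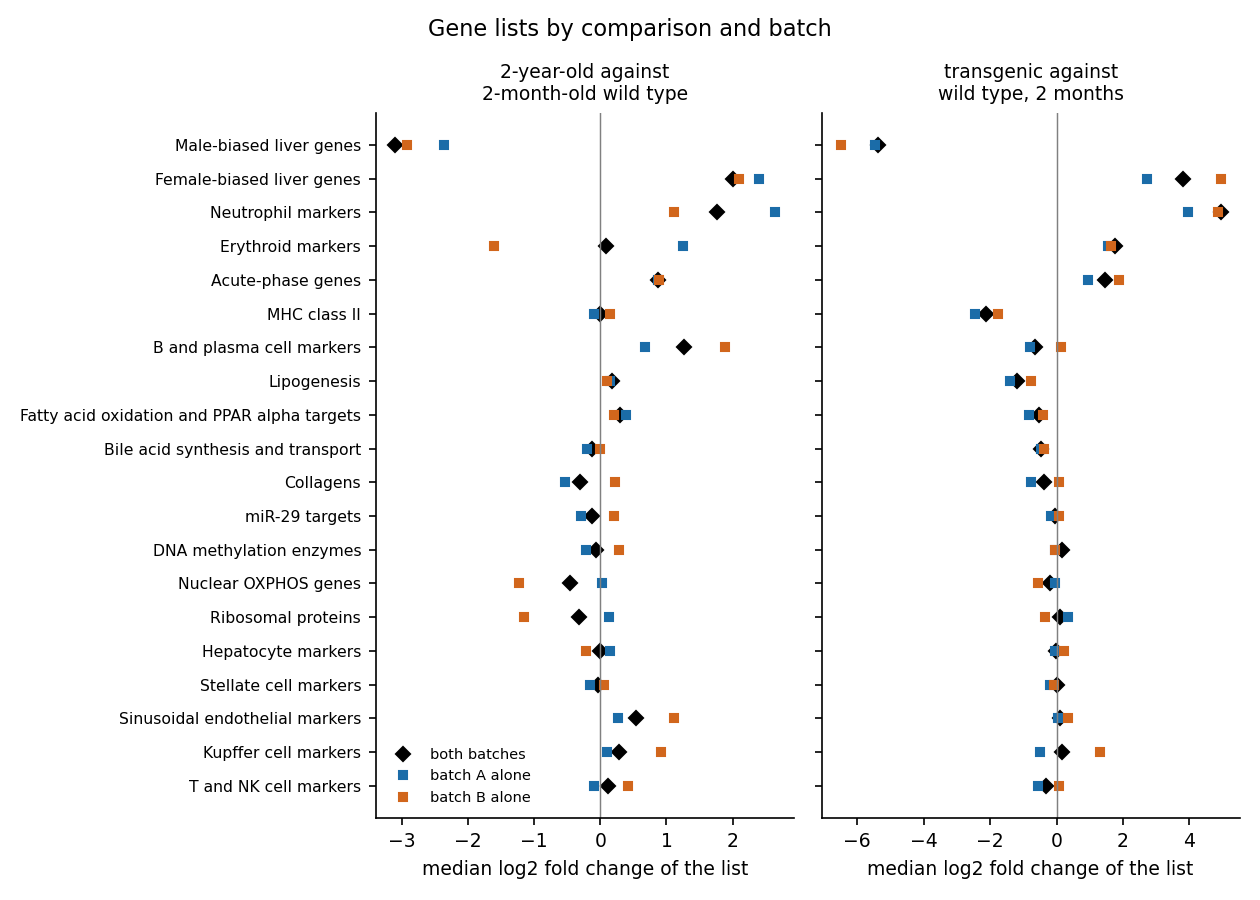
Median log2 fold change of the members of 20 gene lists, on the log2(value + 1) scale, for the age comparison and the transgene comparison. Diamonds are the fit over both batches and squares are fits of batch A or batch B alone. In transgenic livers the male-biased list lies at -5.38 and the neutrophil list at 4.94, on one side of 0 in both batches, while the OXPHOS list in old livers lies at 0.03 in batch A and -1.23 in batch B.

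The transgene was examined next, as transgenic against wild-type liver at 2 months. Transgenic livers had far less of the male-biased messages, including the major urinary proteins, and, in males, more of female-biased messages such as Sult2a1. They had more message of most neutrophil genes and of some acute-phase and red cell genes. Of 10 MHC class II genes 5 fell, and of 20 lipid synthesis genes 6 fell. No list was called with an estimated correlation. At the preset correlation 17 were, where other groupings of the same libraries gave a median of 12, so those p-values overstate the evidence. Fry called 6 lists: male-biased (adjusted p = 9.96e-05), bile acid (0.000155), neutrophil (0.000663), erythroid (0.0324), MHC class II (0.0324) and female-biased genes (0.0386). In total 979 of 14588 genes passed, 421 higher and 558 lower (43.0% higher). Each batch alone called fewer, 495 in batch A and 263 in batch B.

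All 17 measured male-biased liver genes fell (17 adjusted over the list alone), with a median log2 fold change of -5.38 (-5.46 in batch A and -6.50 in batch B). The list's camera adjusted p was 3.74e-26, and with an estimated correlation adjusted p = 0.0741. Counted by sex after the values were seen, 16 of the 17 were lower in all 5 transgenic males than in all 4 young wild-type males. In the 1 transgenic female 12 lay below both young wild-type females and 2 above both. Slco1a1 fell to 43.8 ± 24.7 normalized counts (SD, n = 6), a log2 fold change of -8.05 ± 0.86 (limma adjusted p = 5.72e-05), and Ugt2b38 to 1.164 ± 1.501 (-8.40 ± 0.81, adjusted p = 3.24e-05). Of the 10 largest falls under the naming rule, 8 were major urinary protein genes, which encode pheromone carriers secreted by male liver. Mup19 (chr4:61778324-61782269) fell from 163700 ± 132700 to 511 ± 932 (log2 fold change -9.19 ± 1.16, adjusted p = 0.000211), and Mup15, Mup14, Mup17, Mup16, Mup13, Mup11 and Mup7 had log2 fold changes from -8.64 to -7.80. All 19 measured genes of this cluster (chr4:60066469-62150863) fell, with a median of -7.72, and together they took at most 0.11% of the normalized counts of a transgenic library against 6.456% to 12.688% in the 4 wild-type males of the same age. These genes are near-identical copies, so single values are uncertain and the sum is less affected.

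**Figure D2:**
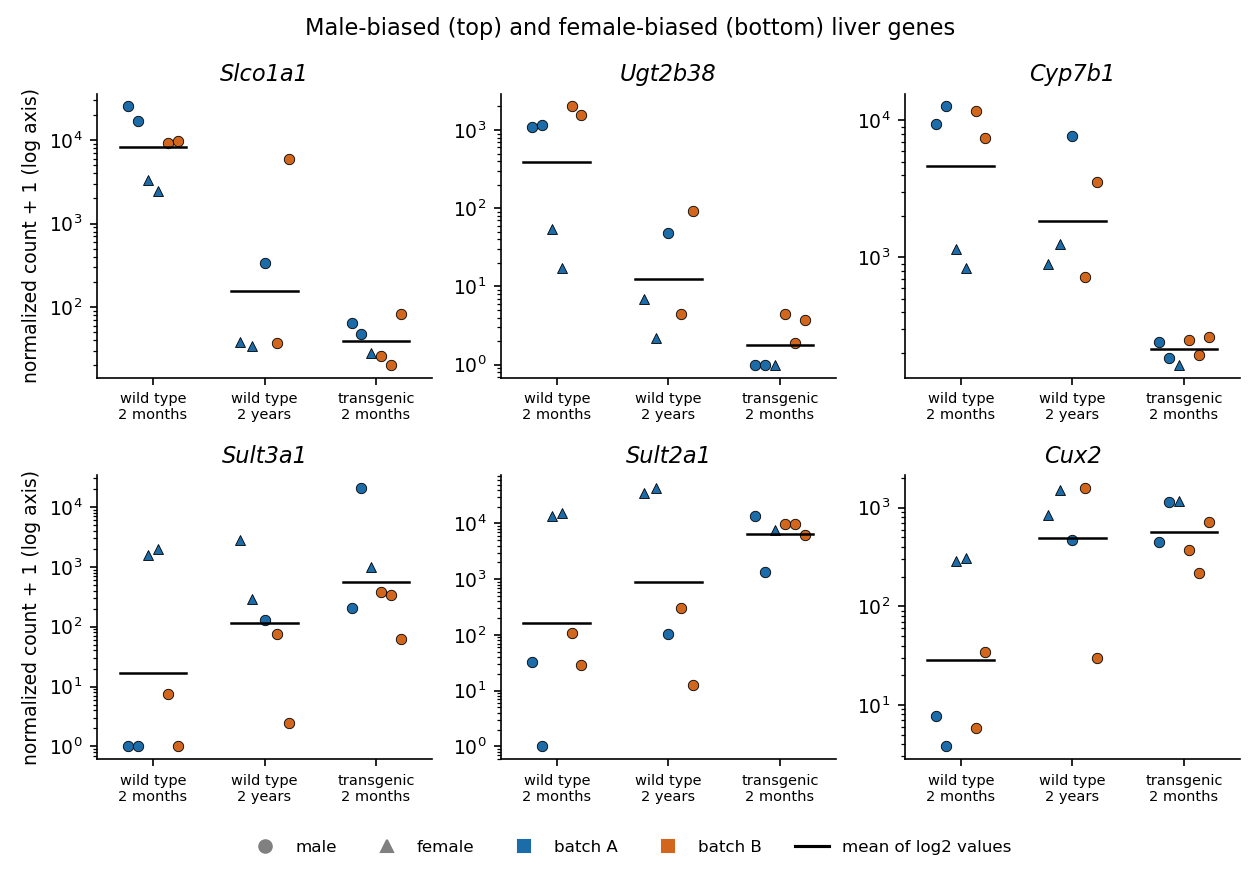
Normalized count + 1 per library, on a log axis, of 3 male-biased genes (top) and 3 female-biased genes (bottom) in the 3 groups. Circles are males and triangles females, colours mark the batch, and bars are means of log2 values. Cyp7b1 lies between 164.0 and 261.4 in the 6 transgenic libraries and at 723.1 or above in all wild-type libraries.

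Of 22 female-biased liver genes, 11 rose and none fell (13 adjusted over the list alone), with a median of 3.79 (2.71 in batch A, 4.94 in batch B; adjusted p = 0.558 with an estimated correlation). The rise is that of males. In counts made by sex after the values were seen, 15 of the 22 were higher in all 5 transgenic males than in all 4 young wild-type males, while in the 1 transgenic female 19 lay below both young wild-type females and 3 above both. The sulfotransferases Sult2a1, Sult2a2 and Sult3a1 rose by 6.40 ± 1.37, 5.97 ± 1.38 and 6.16 ± 1.51. In the same class but outside the list, the oestrogen sulfotransferase Sult1e1 (chr5:87575969-87591594) had the largest named rise, from 35.7 ± 35.4 to 8087 ± 4985 (7.96 ± 0.93, adjusted p = 0.000107). Sult2a5 rose by 6.60 ± 1.09 and the transporter Slc22a26 by 5.39 ± 1.25. The Sult2a genes are close copies, and the adjusted fold changes weigh mostly males, in which these messages were low in young wild type (Sult2a1 at or below 109.4, against 13415.8 and 15133.1 in females). An interaction of the transgene with batch passed for 73 genes. One with sex passed for 189, but with 1 transgenic female a difference between sexes cannot be told from a trait of that animal.

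Genes that act in growth hormone signalling fell in part. The growth hormone receptor Ghr went from 12490 ± 1787 to 4542 ± 1614 (log2 fold change -1.55 ± 0.28, adjusted p = 0.00249). Igfals, the carrier subunit of circulating IGF1, fell by 1.92 on the log2 scale (adjusted p = 0.0103) and Igf1 fell from 16170 ± 2651 to 8418 ± 2078 (-0.92 ± 0.21, adjusted p = 0.016). Igfbp1, an IGF-binding protein raised by fasting and stress, rose (3.07 ± 0.58, adjusted p = 0.00364). In all, 1 of the 17 genes of this axis rose and 3 fell (2 and 3 adjusted over the list alone), and the list itself was not called, with a median of 0.14, a mean of 0.06 and a test direction below 0.

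Of 15 neutrophil markers, 12 rose (14 adjusted over the list alone), with a median of 4.94 (3.94 in batch A and 4.86 in batch B; camera adjusted p = 1.2e-15, and adjusted p = 0.0805 with an estimated correlation). The collagenase Mmp8 rose from 2.28 ± 1.74 to 384.1 ± 358.5 (log2 fold change 6.03 ± 0.90, adjusted p = 0.00061) and lactoferrin, Ltf, from 9.20 ± 17.6 to 1290 ± 1899 (5.38 ± 1.05, adjusted p = 0.0047). Of 10 erythroid markers, 5 rose and none fell (6 rises and 2 falls adjusted over the list alone; median 1.75, adjusted p = 0.591 with an estimated correlation), with the anion exchanger Slc4a1 at 4.38 ± 0.66. Of 19 monocyte and recruited macrophage markers, 3 rose (8 rises and 2 falls adjusted over the list alone; median 0.65, -0.25 in batch A and 1.68 in batch B; called higher, camera adjusted p = 0.00588, and adjusted p = 0.661 with an estimated correlation), among them Chil3 (5.51 ± 0.85) and Itgam (1.97 ± 0.51). Of 16 Kupffer cell markers, the scavenger receptor Marco (chr1:120474538-120505024) rose from 287.9 ± 138.3 to 8725 ± 10080 (3.97 ± 0.41, adjusted p = 3.85e-05). The other 15 did not pass, also when adjusted over the list alone. The list's median was 0.17, at -0.49 in batch A and 1.32 in batch B. The list was called higher (camera adjusted p = 0.0494, adjusted p = 0.772 with an estimated correlation).

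**Figure D3:**
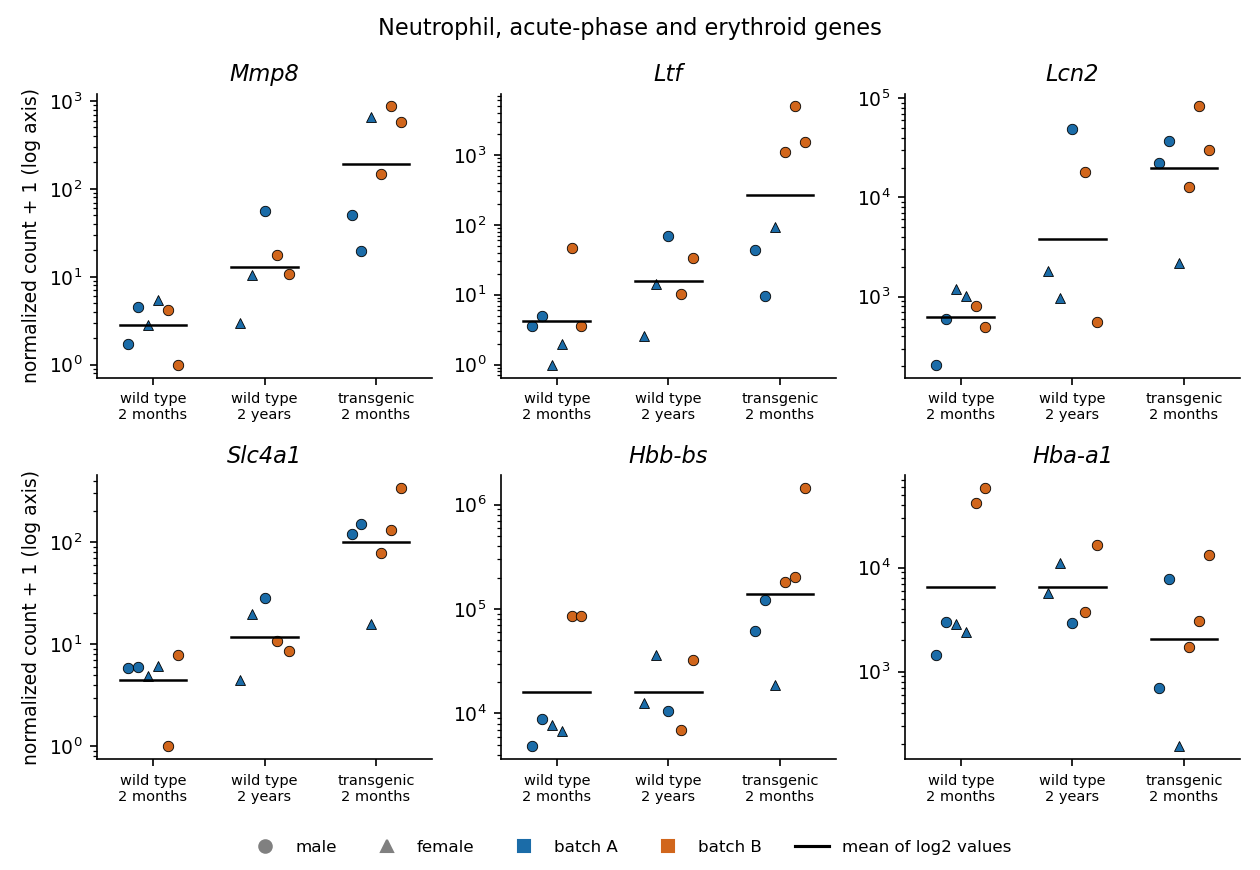
Normalized count + 1 per library, on a log axis, of the neutrophil genes Mmp8 and Ltf, the acute-phase gene Lcn2, and the erythroid genes Slc4a1, Hbb-bs and Hba-a1. Symbols are as in the plot of male- and female-biased genes. Slc4a1 lies at 14.7 or above in the 6 transgenic libraries and at or below 6.8 in the 6 wild-type libraries of the same age.

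Of 28 acute-phase genes, 8 rose (14 adjusted over the list alone; median 1.45, adjusted p = 0.591 with an estimated correlation). Lcn2, lipocalin 2, rose from 717.6 ± 360.0 to 31160 ± 28100 (log2 fold change 4.77 ± 0.97, adjusted p = 0.00638) and Orm2, an orosomucoid, by 4.35 ± 0.96. Of 15 immediate early genes 3 rose and 1 fell (5 and 1 adjusted over the list alone; median 1.08, estimated-correlation adjusted p = 0.661), namely Btg2 (2.69 ± 0.40) and Ier3 (2.31 ± 0.52) among the rises and Cyr61 (-1.39 ± 0.41) as the fall. Of 14 fetal and imprinted genes 3 rose and 1 fell (6 and 1 adjusted over the list alone; median 1.15, estimated-correlation adjusted p = 0.591). The fetal RNA-binding protein Igf2bp3 rose by 3.52 ± 0.73 and Bex1 by 3.31 ± 0.82, and the imprinted noncoding RNA Meg3 fell (-2.52 ± 0.60). In the only transgenic female Igf2bp3 was at 4, against 77.6 to 275.6 in the transgenic males.

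Antigen presentation genes fell in part. Of 10 MHC class II genes, 5 fell (6 adjusted over the list alone; median -2.13, -2.45 in batch A and -1.75 in batch B, adjusted p = 0.569 with an estimated correlation). H2-Eb1 went from 1081 ± 166 to 170.8 ± 91.4 (log2 fold change -2.90 ± 0.52, adjusted p = 0.00262) and H2-Aa by -2.77 ± 0.52. Of 16 MHC class I genes 2 fell (3 adjusted over the list alone; median -0.35, estimated-correlation adjusted p = 0.689), the proteasome subunit Psmb9 at -1.47 ± 0.40 and B2m at -0.88 ± 0.24.

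Lipid and bile acid genes fell on balance. Of 20 lipogenesis genes 6 fell (11 adjusted over the list alone; median -1.19, adjusted p = 0.591 with an estimated correlation), with malic enzyme Me1 at -2.14 ± 0.46 and liver pyruvate kinase Pklr at -2.05 ± 0.52. Of 29 fatty acid oxidation genes 8 fell and 2 rose (14 and 3 adjusted over the list alone; median -0.52, estimated-correlation adjusted p = 0.613). The fatty acid carrier Fabp1 went from 171900 ± 55620 to 18820 ± 31330 (-4.90 ± 1.01, adjusted p = 0.00709) and Acaa1b by -2.54 ± 0.45, while Cyp4a14 (3.46 ± 0.91) and Cd36 (2.17 ± 0.28) rose. Of 20 bile acid genes 7 fell and 2 rose (9 and 2 adjusted over the list alone; median -0.48, estimated-correlation adjusted p = 0.0786). Cyp7b1, an oxysterol hydroxylase, fell by 4.73 on the log2 scale (adjusted p = 3.85e-05), and the transporters Slco1a4 (2.65 ± 0.56) and Abcc4 (2.27 ± 0.32) rose. Of 25 cholesterol genes, Sc5d alone passed (1 adjusted over the list alone), at -1.93 ± 0.49, with a list median of -0.72 and estimated-correlation adjusted p = 0.772.

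Of miR-29 targets and matrix genes few passed, in both directions. Of 52 miR-29 targets 1 rose and 3 fell (1 and 3 adjusted over the list alone), and the list was not called, with a median of -0.04 (camera adjusted p = 0.701). Collagens Col5a3 (-2.14 ± 0.42, adjusted p = 0.0045) and Col1a1 (-1.88 ± 0.46, adjusted p = 0.02) fell, and the pro-apoptotic Bcl2l11 rose (1.75 ± 0.36, adjusted p = 0.00702). Of 21 collagens 3 fell (6 adjusted over the list alone), with Col27a1 at -2.45 ± 0.42. The collagen list was called lower (camera adjusted p = 0.0158, adjusted p = 0.689 with an estimated correlation), with a median of -0.38, at -0.77 in batch A and 0.07 in batch B. Of 36 other matrix genes 2 rose and 1 fell (3 and 3 adjusted over the list alone), and the list was not called, with a median of 0.04 (camera adjusted p = 0.776). Col3a1 (-1.75 ± 0.56), Col4a1 (-0.20 ± 0.25), Eln (-0.45 ± 0.36) and Sparc (-0.03 ± 0.27) did not pass. None of 12 DNA methylation enzymes passed limma's test (0 adjusted over the list alone, 2 at an unadjusted p under 0.05), with Dnmt3a at -0.18 ± 0.32 and Dnmt3b at 0.45 ± 0.37. Of 22 senescence and secretory genes 4 rose and 1 fell (5 and 3 adjusted over the list alone; list not called). Among these, Cxcl1 had 3.62 ± 1.04 and Glb1, the senescence-associated galactosidase, -0.67 ± 0.18. Cdkn2a was at 0.97 ± 1.07 normalized counts, a log2 fold change of -0.27 ± 0.58, Cdkn1a had 1.72 ± 0.68 (adjusted p = 0.15) and Lmnb1 0.02 ± 0.38. Of 28 p53 targets Btg2 rose and Perp fell by 0.998 on the log2 scale (adjusted p = 0.0235). None of 43 OXPHOS genes passed limma's test (1 lower at an unadjusted p under 0.05; list median -0.21, estimated-correlation adjusted p = 0.889), and Ndufb3 had -0.62 ± 0.28.

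At the preset correlation 5 lists of other liver cells were not called, while the monocyte and Kupffer lists were. No difference between lists was tested. The camera adjusted p was 0.0494 for the Kupffer list, against 0.118 for the endothelial and 0.141 for the B and plasma list. With an estimated correlation none of these lists was called. List medians were 0.02 for 18 stellate cell markers, 0.09 for 20 sinusoidal endothelial markers, -0.32 for 18 T and NK cell markers, -0.66 for 17 B and plasma cell markers and -0.01 for 25 hepatocyte markers. Single members did pass: 2 endothelial and 1 T and NK marker rose, 1 B and plasma marker rose and 2 fell, and 1 hepatocyte marker fell. Adjusted over the list alone, 3 stellate markers rose and 3 B and plasma markers fell.

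Seed matches were counted because a microRNA acts on messages that carry them. Of 12927 genes with a 3′ UTR, 1989 had the 7-base miR-29 site. In transgenic livers these genes differed from the rest by -0.0084 on the log2 scale (exact permutation over 180 label arrangements, two-sided p = 0.6611, smallest possible 0.0056). The site ranked 6552 of 15770 7-mers from the lowest t value. Restricting to the 8-base site, in 425 genes, gave -0.0723 (exact permutation p = 0.0222), while the 7-base value was 0.0181 in batch A and -0.0513 in batch B. In old against young livers the 7-base site gave -0.0498 (exact permutation p = 0.0185 over 108 arrangements) and ranked 671 of 15770, and the 8-base site gave -0.0752 (exact permutation p = 0.0093). Without the adjustment for UTR length and GC content the 7-base value was -0.0034 (exact permutation p = 0.9352).

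The 2 sets of changes were then set side by side. Of the genes called in both, 9 had one direction, 6 higher and 3 lower in old and in transgenic livers, and 3 had opposite directions. Cd36, Abcc4 and Cyp2c38 rose in both, as did Ighm, and Slco1a1, Ugt2b38 and C8b (-1.75 ± 0.25 in transgenic livers) fell in both. Prelid2 and the antisense gene Gm11695 also rose in both and were chosen after their values were seen. Raet1e and Tiam2 rose with age and fell in transgenic livers (-2.21 ± 0.33 and -3.05 ± 0.23). The age calls of these genes were not equally stable. Of 36 alternatives, 25 lost the age call of Abcc4, 25 that of Tiam2, 18 that of C8b, 15 that of Ugt2b38 and 10 that of Slco1a1. For Cd36, Cyp2c38, Raet1e and Ighm 6, 5, 3 and 2 lost it. Independent lists of these sizes would share 0.40 higher and 0.27 lower genes and 0.54 that rise with age and fall in transgenic livers. With each comparison given its own 3 of the 6 controls, the count was 0 to 1 over 8 splits, in which 0 to 5 genes were called with age.

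Across the 14588 genes, which are not independent replicates, the 2 log2 fold changes had a Pearson correlation of 0.557 and a Spearman correlation of 0.49. Simulated unchanged groups that share the controls gave 0.438 ± 0.211 and 0.404 ± 0.236 (SD, 100 draws). The covariance was 0.292 against a simulated 0.0917 ± 0.0576 (SD), a difference of 0.201. Of the 100 draws 0 were as large (highest 0.265). With split controls the Pearson correlation was 0.379 to 0.444, the Spearman correlation 0.277 to 0.359 and the covariance 0.226 to 0.252. The Pearson correlation was 0.357 in batch A alone. In the authors' deposited tables, which call more genes, 143 genes were called in both, 130 with one direction (74 higher and 56 lower, where independent lists would share 9.9 and 7.93) and 13 with opposite directions. Both comparisons use the young wild type as control, so their lists are not independent. No count with split controls was made for them, so the excess does not show a shared response.

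**Figure D4:**
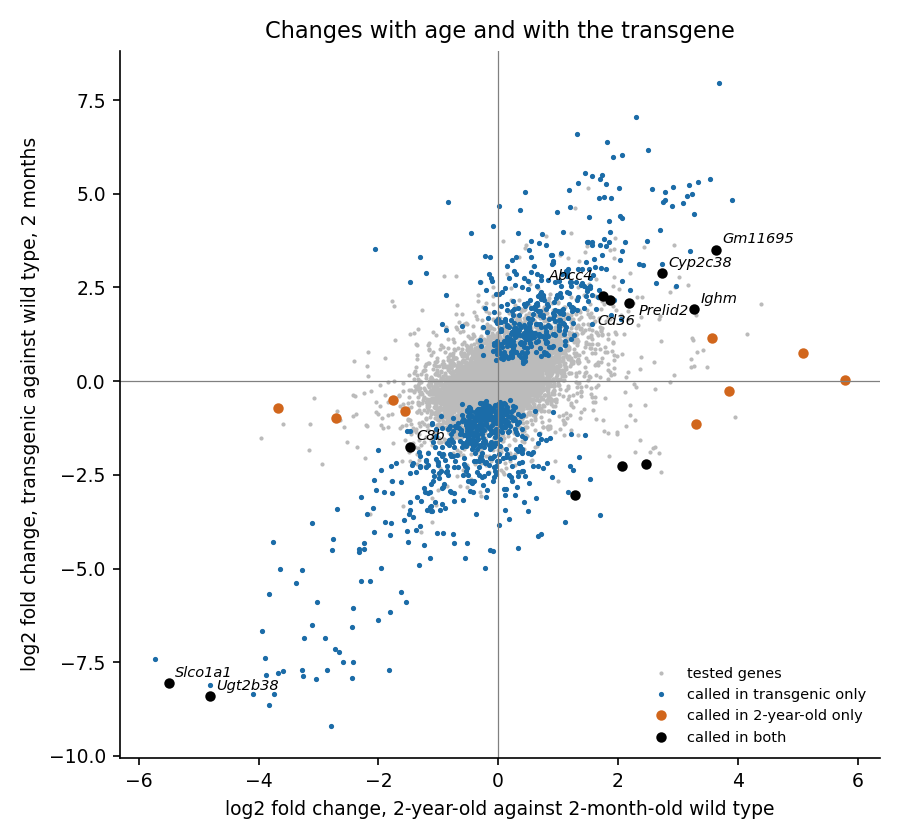
Each point is 1 of 14588 genes, by its log2 fold change in old against young wild type (x axis) and in transgenic against wild type at 2 months (y axis). Black points are called in both comparisons, blue ones in the transgenic comparison and orange ones in the age comparison. Slco1a1 and Ugt2b38 lie far below 0 on both axes, while the 3 genes with opposite directions, not labelled, lie to the right and below 0.

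Transgenic livers were also compared directly with 2-year-old wild type, in which the shared controls cancel. Transgenic livers had less message of some fatty acid oxidation, MHC class II and B cell genes than old livers and even less of some male-biased ones. In total 372 genes differed, 104 higher and 268 lower in transgenic livers. Of 29 fatty acid oxidation genes 7 were lower and none higher (18 adjusted over the list alone; median -0.87, estimated-correlation adjusted p = 0.189). Of 17 male-biased genes 4 were lower (13 adjusted over the list alone; median -2.55, estimated-correlation adjusted p = 0.189), and of 10 MHC class II genes 5 were lower (7 adjusted over the list alone; median -2.09, estimated-correlation adjusted p = 0.281). Only 2 lists were called with an estimated correlation, both at adjusted p = 0.0308. These were the 17 B and plasma cell markers, of which 4 were lower (11 adjusted over the list alone; median -1.82), and the 20 bile acid genes, of which 1 was lower (7 adjusted over the list alone; median -0.48). Of 15 neutrophil markers 2 were higher (7 adjusted over the list alone; median 2.11, estimated-correlation adjusted p = 0.281). Batch A alone called 175 genes and batch B alone 45.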

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

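Of the tests in this part, those of Xist, of near-identical copies, of batch for the male-biased genes, of list members by sex, of blood, of hepatocyte share, of primary granule genes and of transcript length were chosen only after the result was seen.

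A total of 19 named-gene values lay far from the rest of their group, out of 270 gene-group sets tested (7%). Chance gives about 1 in 20 only in uniform groups. These groups mix sexes and batches, so that rate does not apply to them. In the young wild type these were Cdh19 in library 3 (9.8, others 0 to 0.6), Igf1 in library 1 (11387.5, others 15512.6 to 18350.8) and Slc4a1 in library 5 (0, others 3.9 to 6.8). In the 2-year-old wild type they were Sort1 in library 2 (48.7, others 110.6 to 134.2) and 3 genes in library 5, a male: Ighg2c (28.8, others 336.4 to 692), Slc22a26 (46.3, others 2365.9 to 5206.9) and Slco1a4 (337.1, others 2797.2 to 3516.6). In transgenic livers they were Cdh1 in library 1 (1203.3, others 377.2 to 501.3), Ighm in library 2 (142.4, others 575.1 to 1213.3), Sult2a1 in library 2 (1322, others 6086.1 to 13730.3), Ighg2c in library 3 (215.3, others 14.3 to 31.9), Igf2bp3 in library 3 (4, others 77.6 to 275.6) and Cdkn1a in library 4 (770.3, others 2421.2 to 3283.1). The remaining 6 were major urinary protein genes, all highest in transgenic library 6: Mup19 (2412), Mup15 (1385.8), Mup14 (2201.8), Mup17 (1144.4), Mup11 (1283.8) and Mup7 (5314). These share near-identical copies, so the 6 are not separate events. Transgenic library 3 is the only transgenic female.

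For 4 named genes an interaction of the transgenic effect with sex or batch passed. The effect in females minus that in males was -8.2 for Sult2a5 (adjusted p = 0.011), -9.92 for Sult2a2 (adjusted p = 0.0407) and -8.86 for Slc22a26 (adjusted p = 0.0451), and each rests on 1 transgenic female, so a difference between sexes cannot be told from a trait of that animal. Slc22a26 was at 2173.1 in that female against 5105.2 and 5226 in the 2 young wild-type females, and at 2178.8 or above in the 5 transgenic males against 32.9 or less in the 4 young wild-type males. For Cdkn1a the effect in batch B minus that in batch A was 4.5 (adjusted p = 0.0414), with -0.146 in batch A and 4.351 in batch B, higher in 3 of 3 transgenic libraries of batch B.

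Male-biased genes were lower in transgenic livers, and female-biased genes were higher in transgenic males. In the 1 transgenic female 12 of 17 male-biased genes lay below both young wild-type females and 2 above both. Of the 22 female-biased genes 19 lay below both and 3 above both in that animal. The tables argue against mislabelled or mixed sex, since the highest Xist value among transgenic males was 64.4, against shared reads, since all 7 list members without a near-identical copy fell, and against kit and site, since the within-batch median nearest 0 was -5.46. A shift of sex-dependent expression as a whole stays open. Genes chosen by sex in batch A wild type moved apart by 1.56 in the batch B transgenic comparison, with a median of -1.28 for 184 male-biased genes and 0.28 for 187 female-biased ones, and the latter did not reach the bound of 0.5 set for it. A change of growth hormone signalling may lie behind this and was not tested.

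Of 15 neutrophil markers 12 rose in transgenic livers, and of 10 erythroid markers 5 rose (6 rises and 2 falls adjusted over the list alone). A lower share of hepatocytes would raise the markers of other cells alike, and the highest median of the stellate, endothelial, T and NK, and B and plasma lists was 0.09 against 4.94 for neutrophils (0.17 for Kupffer cells and 0.65 for monocytes and recruited macrophages, which camera called higher). Blood left in the tissue would raise all its abundant messages and stays open, since these went both ways (median -1.09): Hbb-bs and Hbb-bt rose (2.76 and 2.65, adjusted p = 0.0301 and 0.0385), while Hba-a1, Hba-a2 and Alas2 did not pass (-2.09, -2.08 and -1.09, adjusted p = 0.16, 0.161 and 0.315). Immature granulocytes in the liver may contribute and this stays open, since of the 3 primary granule genes 1 was called, Mpo (log2 fold change 5.05, adjusted p = 0.0101), while Prtn3 (3.60, adjusted p = 0.0567) and Elane (2.73, adjusted p = 0.112) were not. Mpo was at 912.8 or above in the 3 transgenic libraries of batch B and at 15.9 or below in the 3 of batch A.

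The fold changes of old and of transgenic livers went together across genes, with a correlation of 0.557. A transcript length and GC trend and sex-dependent genes stay open: the correlation was 0.553 with the trend removed and 0.515 over the 13221 genes without a sex difference, but the bound set for both, 0.5 times 0.557, lies below the 0.438 that shared controls give alone, so these tests decide nothing. Shared controls stay open, since with split controls the mean was 0.411 and the lowest of 8 values lay above the bound set in advance by less than the jackknife standard error of 0.165, and 10 of 100 simulated splits of unchanged groups reached that lowest value. For the covariance 0 of 100 simulated splits reached the lowest observed value (0.226, simulated highest 0.199). With shared controls 0 of 100 simulated draws reached the observed 0.292 (highest 0.265). In 7 of 100 groupings of the real libraries, the real one included, the covariance was 0.292 or more. Those groupings spread the transgenic libraries over all groups, so they carry the transgene effect and give no level for unchanged groups. The shared controls and a shared response cannot be told apart by the correlation.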

How the results depend on the processing

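Chosen only after the data were seen were the tests with the length and GC trend removed, with 1 residual component, without the 2 batch B libraries nearest batch A (2-year-old 4 and transgenic 4), without the transgenic female, and the further settings of the interaction tests.

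Transgenic 3 is the only transgenic female, so the fits without it and without the transgenic female are the same. The counts of alternatives, kept calls and reversals below include that fit under both names. Of 36 alternatives for the count of 21 genes changed with age, 15 stayed within 1.5 times. The others gave 9 with a mean of at least 50, 10 with no batch term, 9 with no sex term, 1 in batch A, 0 in batch B (limma, 3764 genes at an unadjusted p under 0.05), 41 in males, 37 with quality weights, 293 with 1 residual component, 10 without the 2 batch B libraries nearest batch A, 37 without the transgenic female, 10 with only the groups compared and 280 in the authors' table. Leaving out 1 library gave 9 to 37: 9, 10 and 12 without old 2, 3 and 4, 12 without young 1, 2 or 3, 13 without young 5 and 37 without transgenic 3. For the 9 genes called in both with one direction the values were 5 with a mean of at least 50, 5 with quantile normalization, 3 with no batch term, 3 with no sex term, 1 in batch A, 0 in batch B, 28 in males, 18 with quality weights, 183 with 1 residual component, 3 without the nearest batch B libraries, 18 without the transgenic female and 130 in the authors' tables. Leaving out 1 library gave 3 to 18: 3, 5, 5 and 14 without old 2, 3, 4 and 5, 5, 4, 4 and 5 without young 1, 2, 3 and 5, and 18 without transgenic 3. The 979 genes changed with the transgene stayed within 1.5 times in 31 of 36 alternatives. It was 541 with no batch term, 495 in batch A, 263 in batch B, 2114 with 1 residual component and 2211 in the authors' table, and 653 to 1311 leaving out 1 library. The 372 that differ between transgenic and old livers became 176 with no batch term, 175 in batch A, 45 in batch B, 175 in males, 859 with quality weights, 730 with 1 residual component, 570 without the nearest batch B libraries and 120 with only the groups compared. Leaving out 1 library gave 161 to 525, with 231 and 161 without old 1 and 5 and 244 without transgenic 5. Fits of 1 batch have fewer libraries, and the residual component lowers the error while leaving the fold changes as they were. For the other settings, males included, the cause was not tested. The correlation of 0.557 was 0.357 in batch A and 0.442 to 0.6 leaving out 1 library. The 17 and 17 lists were 0 and 0 by camera with an estimated correlation (5 and 3 at an unadjusted p under 0.05), 3 and 6 by fry, and 15 to 25 and 13 to 18 leaving out 1 library.

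With the replicate number as a block the counts were 11 with age, 796 with the transgene, 247 between transgenic and old, and 5 in both. The numbers were not taken to pair the libraries, because the rule asks every paired correlation to lie above 0.1: 13 of 16 did (range -0.23 to 0.59), and 5 of 17 libraries correlated best with their own number. These correlations were taken after removal of group means alone, so libraries of the same batch can correlate through it. Young 4, from batch A, had -0.23 with old 4 and -0.22 with transgenic 4, both from batch B. The correlations therefore cannot tell a pairing from batch, and a partial pairing is not excluded. Of the 17 named genes called with age, 9 lost the call with the block.

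Interaction counts depended strongly on settings, and the cause was not tested. Batch by age, 3 genes, was 13 with a pseudocount of 0.5, 1 with 10, 52 with no filter and 0 with quantile normalization. It ran from 0 to 237 leaving out 1 library: old 1, 2, 3 and 5 gave 1, 0, 26 and 237, young 1, 3, 4, 5 and 6 gave 1, 0, 1, 20 and 37, and transgenic 1 to 6 gave 16, 1, 16, 168, 1 and 39. Sex by age, 2 genes (Fmo2 and Cyp2c54), was 4 with a pseudocount of 10, 5 with no filter and 0 with quantile normalization, and ran from 0 to 16: old 2, 3, 4 and 5 gave 4, 0, 0 and 16, young 1 to 6 gave 5, 0, 0, 1, 0 and 1, and transgenic 2, 4, 5 and 6 gave 0, 1, 0 and 1. Batch by transgene, 73 genes, was 47 with a pseudocount of 10, 147 with no filter, 27 with a mean of at least 50 and 33 with quantile normalization, and ran from 3 to 238: young 1, 3 and 4 gave 8, 4 and 3, and transgenic 1, 3, 4 and 5 gave 238, 31, 36 and 20. Sex by transgene, 189 genes, was 440 with no filter and ran from 12 to 408: young 3, 4, 5 and 6 gave 12, 17, 117 and 113, and transgenic 2 gave 408. It could not be fitted without the transgenic female.

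The seed-site difference with the transgene, -0.0084, was -0.0723 for the 8-base site (exact permutation p = 0.0222), 0.028 with no UTR adjustment, 0.0054 with a mean of at least 50 and 0.0181 in batch A, and -0.015 to 0.0044 leaving out 1 library (0.0044 without young 6). With age, -0.0498, it was -0.0034 with no UTR adjustment (exact permutation p = 0.9352), -0.0217 in batch A and -0.1 in batch B, and -0.0569 to -0.0381 leaving out 1 library, with exact permutation p = 0.0556 without old 2 or 3 or young 1 or 2. Fewer libraries allow fewer arrangements, and for the UTR adjustment the cause was not tested.

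Over 106 named gene comparisons and 3805 alternative values, 3326 kept direction and side of the threshold, 403 lost the call, 27 gained it and 49 reversed. Of 58 named genes called with the transgene 10 held under all alternatives, and of 17 called with age 0 did. None of the 58 or the 17 reversed. The reversals were all in genes not called. With age they were Rpl38 in batch A (0.016), Col4a1 in batch A (-0.02), with quality weights (-0.07), with the trend removed (-0.021), without the nearest batch B libraries (-0.009) and leaving out 1 library (-0.018 to 0.204), Dnmt3a in batch A (-0.093) and leaving out 1 library (-0.039 to 0.371), Dnmt3b leaving out 1 library (-0.431 to 0.091), Cdkn1a in batch A (-0.482) and leaving out 1 library (-0.214 to 0.7), and Igf1 in batch B (-0.257). With the transgene they were Sparc with quantile normalization (0.124), no batch term (0.005), batch B (0.048), males (0.122), quality weights (0.028), the block (0.046), without the transgenic female (0.205) and leaving out 1 library (-0.26 to 0.205), Dnmt3a in batch A (0.127) and leaving out 1 library (-0.409 to 0.038), Cdkn1a in batch A (-0.146), Cdkn2a in males (0.028), with the block (0.072), without the transgenic female (0.014) and leaving out 1 library (-0.488 to 0.044), and Lmnb1 with quantile normalization (-0.074), upper-quartile rescaling (-0.001), batch A (-0.722), quality weights (-0.144), the block (-0.067), the trend removed (-0.034), without the nearest batch B libraries (-0.199) and leaving out 1 library (-0.208 to 0.34). The cause was not tested. Depth is unknown, so what it limits could not be computed.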

Other observations

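In this part the globin ratio test and the groupings within batch and sex were chosen only after the result was seen, and the other groupings were planned.

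Red cell messages did not move as 1 group in transgenic livers. The β-globin genes Hbb-bs and Hbb-bt rose (log2 fold changes 2.76 and 2.65, limma adjusted p = 0.0301 and 0.0385), while the α-globin genes Hba-a1 and Hba-a2 had -2.09 and -2.08 (adjusted p = 0.16 and 0.161) and did not pass. The ratio of summed β to summed α messages was 3.41 to 72 in the 6 transgenic libraries and 0.687 to 1.28 in the 11 wild-type libraries. Between transgenic and young wild-type libraries the adjusted difference was 27.9-fold (exact permutation p = 0.0056, the smallest that 180 arrangements can give). In transgenic library 6 β-globin took 3.99% of the total.

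The 3 old males differed from each other in sex-biased genes, although Xist and the Y-linked genes matched their labels. Library 4 had Slco1a1 at 35.8 and Cux2 at 1573.9, near the old females (Slco1a1 at 37.5 and 32.7), while its Sult2a1 was at 297.5 against 35395.6 and 43026.7 in them. Library 5 had Slco1a1 at 5908.5 and Cux2 at 28.7, and library 3 lay between for Slco1a1 (333.5) and Cux2 (464.6). The major urinary proteins took 3.241%, 0.023% and 3.042% of the total in libraries 3, 4 and 5. These libraries were singled out after their values were seen.

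Other groupings of the same libraries, 100 for each result with the real one included, were tested with a rule set in advance. They were not kept within batch and sex, and unbalanced groupings have less power, so their counts run low. Fewer than 5 in 100 were as large for the 979 genes changed with the transgene (1 grouping as large, highest other 46), the 21 changed with age (1, highest other 2) and the 372 between transgenic and old (2, highest other 523). Only for the transgene is chance called excluded, for the reason given in the next paragraph. For the 9 called in both (1, highest other 0) the groupings decide nothing, since 0 of the others had calls in both comparisons (limma). Chance cannot be excluded for the correlation of 0.557 (38 groupings as large, highest other 0.805). Its groupings spread the transgenic libraries over all groups, so they give no level for unchanged groups. Nor can chance be excluded for the 17 lists with age (21, median of the others 11, highest 23). The same holds for the 17 lists with the transgene (15, median of the others 12, highest 20).

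Groupings kept within batch and sex were then drawn for the 3 gene counts. For the transgene 1 of 100, drawn from 180 arrangements, was as large, the real one (979, highest other 1). This is the smallest share these draws can give. By the rule of fewer than 5 in 100, chance is called excluded to that limit, with libraries taken as separate. For age 2 of 100 were as large, and the other called 1263 genes against 21. It kept the labels of the females and exchanged old males 3, 4 and 5 with young males 2, 5 and 6. This exchange took in all wild-type libraries of batch B, so a structure by sex cannot be told from one by batch. The interaction tests called 2 genes for sex by age and 3 for batch by age, and the cause was not tested further. With a count so far above the real one, the count of 21 by itself says little about age. Chance is not called excluded for it. Between transgenic and old livers 2 of 90 were as large, and the other called 523 against 372, with old males 3, 4 and 5 exchanged with transgenic males 1, 5 and 6. The cause was not tested here either, so the count of 372 by itself says little, and chance is not called excluded for it.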
